A study of Arabidopsis thaliana with 64 samples.

How the data were processed

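RNA was measured in 64 libraries of *Arabidopsis* parents, F1 hybrids and F4 lines, 36 at 15 DAS (aerial tissue of seedlings) and 28 at 28 DAS (the 4 largest leaves). Each library came from a pool of 5 plants, and each of the 32 groups had 2 pools. Per the protocols, plants were grown in 16 h of light and 8 h of dark at 22 and 18 °C, moved to soil at 18 DAS, and split into 2 batches under different light tubes. The smallest seedlings were the 5 smallest of 50. The protocols place 1 S line in batch 1 without saying which, so S1-1 and S2-1 were given no batch. Per the protocols, C24 and Ler pools lettered A and B belong to batch 1 and those lettered C and D to batch 2.

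Reads were checked with FastQC, mapped to TAIR10 and counted per gene by the authors, and the deposited tables hold these raw counts for 33321 gene rows. The mapping and counting programs, their versions and the handling of strand are not given in the sources used here. The deposited normalised tables hold a score, which is each library's counts multiplied by 1 factor and rounded by the authors, and they were used only to check column names. A combined table was not used here because many of its column names disagree with the tables of each age. Gene names and chromosomes came from a reference gene table, in which 32565 of the gene rows were found (125 chloroplast and 143 mitochondrial genes).

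Counts were analysed with edgeR 4.0.16 in R 4.3.3 with limma 3.58.1. Genes were kept by filterByExpr by group, libraries were scaled by trimmed mean of M values (TMM), and 1 quasi-likelihood model per age held all groups. It tested 30207 genes at 15 DAS (biological coefficient of variation 0.177) and 27844 at 28 DAS (0.225). Two-sided quasi-likelihood F tests were adjusted by Benjamini-Hochberg (BH) over all tested genes, and genes below 0.05 were called. The standard error of a log2 fold change was its size divided by the square root of F. Mid-parent libraries were made per batch and age by scaling a C24 and a Ler library, paired by letter, to their TMM effective size and averaging and rounding the counts, 2 per batch. Models with mid-parent libraries tested 30082 genes at 15 DAS and 27720 at 28 DAS, and a model of both ages tested 30287. The comparisons were Ler against C24, the F1 against the mid-parent and against both parents, the 4 L lines of a batch (equal weights on the log scale) against the mid-parent and the F1, S1-1 and S2-1 against the batch 1 mid-parent, the S lines against the batch 1 L lines, the smallest seedlings against others of their parent, batch 2 against batch 1 within each parent, and the difference of F1 deviations between batches and ages. A gene lay outside both parents if the F1 passed against both in 1 direction. For levels of single lines, chosen after the data were seen, genes called with a log2 difference above 4 in the parents of batch 2 at 15 DAS and of both batches at 28 DAS were placed at the parental level below a position of 0.25 or above 0.75 between the parents.

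Gene lists were 15 pathway lists (salicylic acid 28 genes, jasmonate 24, auxin 40, PIF and shade 17, clock 25, photosynthesis 32, cell wall 22, cell cycle 31, flowering 24, glucosinolate 26, flavonoid 18, cold and drought 17, heat shock 14, senescence 15, ethylene 13) and 3 marker lists (flower organ 8, root 9, shoot meristem 8). They were tested with camera of limma on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted by BH over the 18 lists of a comparison, and again with the correlation estimated. Members were counted as called over all genes and also when adjusted over the list alone.

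Before the data were examined, a rule for named genes was fixed: called genes with a mean of at least 1 CPM and no overlap of libraries, the 5 largest rises and 5 largest falls (for the parents, by adjusted p), up to 4 members of lists called or with at least 3 calls, and PR1, ICS1, PIF4, YUC8, IAA29, CCA1, LHY, TOC1, FLC and FT. From these the report names a part, chosen after the values were seen, with preference for calls held when each library was left out, and their calls lost with a library left out are named. A gene withheld for evaluation is not reported here. The comparisons, tests, lists and most alternatives were also chosen before the data were examined. The alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter, nuclear genes only, libraries of the batch only, the replicate letter as a replicate block, crossed letters or a log-scale mean in the mid-parent, other mid-parents or lines for the S lines, and each library left out in turn. Lines averaged as counts, exchanged Ler pools, and a pair of near-identical libraries left out were added after the data were seen.

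The method was tested on simulated data with 200 genes changed, at the depth and spread of these libraries. For the F1 against the mid-parent, 67.2, 56.7, 38.8 and 43.3% of 2-fold changes and 93.9, 92.4, 86.4 and 92.4% of 4-fold changes were recovered (15 DAS batches 1 and 2, 28 DAS batches 1 and 2). For the L lines 91.0, 76.1, 52.2 and 64.2% of 2-fold changes were recovered, and 0 to 4 unchanged genes were called per comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.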

Results

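RNA was sequenced from pools of *Arabidopsis* plants of the inbred parents C24 and Landsberg erecta (Ler), their 2 reciprocal F1 hybrids, and F4 lines with labels that begin with L (8 lines, hybrid mimics per the protocols) or S (2 lines). The 64 libraries formed 32 groups of 2 pools each, 18 groups (36 libraries) at 15 days after sowing (DAS) and 14 groups (28 libraries) at 28 DAS. Each pool held 5 plants, so the p-values measure spread between pools and not between plants. Errors and p-values of averages over lines leave out differences between the lines. Batch 1 held C24, Ler, C24xLer and lines L1-1, L1-2, L2-1 and L2-2, and batch 2 held C24, Ler, LerxC24 and lines L3-1, L3-2, L4-1 and L4-2. Lines S1-1 and S2-1 and the smallest C24 and Ler seedlings were sampled at 15 DAS only. Libraries held 36324848 to 256721442 counted reads and 28740 to 31401 detected genes. Organelle genes took 0.0247 to 0.675% of the reads. Each F1 and line was set against in silico mid-parent libraries, which were averages of 1 C24 and 1 Ler library of the same batch and age. Reads were mapped to the Columbia reference (TAIR10), so low expression of a C24 or Ler gene cannot be told from sequence divergence. Values are CPM (counts scaled to library size), mean ± SD, and fold changes are log2 ± standard error.

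At 15 DAS the floral repressor FLC separated the parents more sharply than any other flowering gene. In batch 1 Ler held 1.21 ± 0.18 CPM (n = 2) and C24 81.5 ± 12.3 (n = 2), a log2 fold change of -6.07 ± 0.23 (edgeR, Benjamini-Hochberg (BH) adjusted p = 1.57e-13). In batch 2 the values were 0.851 ± 0.166 and 104 ± 4.35 CPM (-6.98 ± 0.25, edgeR, BH adjusted p = 2.09e-14). FRI, an activator of FLC, was lower in Ler by 0.65 and 1.14 log2 units, and SOC1, a floral activator that FLC represses, was higher by 2.25 and 2.26. Without C24 pool A or Ler pool B the batch 1 FRI call was lost, and without C24 pool B or Ler pool A the batch 1 SOC1 call was lost. The glucosinolate side-chain genes took opposite sides, as AOP2 fell from 398 ± 73.1 to 6.24 ± 1.83 CPM and AOP3 rose from 1.06 ± 0.02 to 116 ± 100 CPM in batch 1. Over the alternative settings these log2 differences ran from -8.05 to -5.72 for AOP2 and from 5.42 to 7.46 for AOP3. MYB29, a regulator of aliphatic glucosinolates, was lower in Ler in both batches (-1.12 ± 0.19 and -2.01 ± 0.20). The myrosinase gene TGG2 was lower in Ler of batch 2 (10.3 ± 1.48 against 2214 ± 293 CPM), and in batch 1 it held 776 ± 650 CPM in Ler (1236 and 316 in pools A and B) and 1984 ± 308 in C24.

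Of the 25 measured glucosinolate genes, 1 rose and 6 fell in Ler of batch 1 (1 and 9 when adjusted over the list alone). That list was called lower by camera (median -0.37, BH adjusted p = 0.0013), with adjusted p = 0.481 with an estimated correlation. Flower-organ genes were called higher in both batches, with 2 of 8 rising in batch 1 and 5 of 8 in batch 2, the same counts as when adjusted over the list alone. Their camera BH adjusted p in batch 1 was 0.0013, with adjusted p = 0.287 with an estimated correlation. In batch 2 these were led by AP3 (2.57 ± 0.39), LFY (1.45 ± 0.27), AP1 (2.18 ± 0.43) and SEP1 (1.24 ± 0.23), camera BH adjusted p = 0.000262 and adjusted p = 0.135 with an estimated correlation. In batch 1 SEP1 rose by 1.00 ± 0.22, a call lost without C24 pool B or Ler pool B. Shoot-meristem genes rose in batch 2 (4 of 8, for example CLV1 by 0.76 ± 0.15), camera BH adjusted p = 0.0132 and adjusted p = 0.357 with an estimated correlation. STM was among them (12.1 ± 0.11 against 5.28 ± 0.89 CPM), a call lost without C24 pool C or Ler pool C. Salicylic-acid genes were called lower in batch 2, where 0 of 28 rose and 4 fell (camera BH adjusted p = 0.00507, adjusted p = 0.912 with an estimated correlation). Heat-shock genes had 2 rises and 1 fall in batch 2 and no camera call (0.984), with a median of 0.04 and a mean of -0.07. Cell-cycle genes moved both ways in batch 2, with CYCB1;4 (1.14 ± 0.17) and the syntaxin KN (0.82 ± 0.14) higher and CDKB1;2 (-1.07 ± 0.14) lower in Ler.

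Over all genes edgeR called 1168 higher and 819 lower in Ler of batch 1, and 2715 and 2954 in batch 2, at 15 DAS. The Ler pools of batch 1 carried transcripts that other Ler pools lacked, and with the smallest Ler pools in their place 1458 genes were higher and 1631 lower. The fold changes of the 2 batches had r = 0.601, and 749 rises and 642 falls were shared. Leaving out 1 library moved the batch 1 total to 1089 (C24 A), 1188 (C24 B) or 1103 (Ler B). In batch 2 the total became 3647 (C24 C), 2964 (C24 D), 3232 (Ler C) or 3606 (Ler D). The genes AT2G24755 and AT2G24760 rose by 5.78 ± 0.21 and 7.21 ± 0.30 in batch 1, but they overlap and cannot be told apart because strandedness was not given in the sources used here. The resistance-type gene CSA1 held 3.56 ± 0.36 CPM in Ler and 94.3 ± 4.58 in C24 of batch 2 (-4.72 ± 0.19).

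At 28 DAS, leaves of Ler had much less transcript of the salicylic-acid pathway than leaves of C24. ICS1, which encodes isochorismate synthase of salicylic-acid synthesis, held 21.3 ± 6.47 CPM in Ler and 69.5 ± 8.83 in C24 of batch 1 (-1.71 ± 0.22, n = 2 and 2, edgeR, BH adjusted p = 2.94e-05). In batch 2 the values were 22.7 ± 0.04 and 67.1 ± 14.2 CPM (-1.56 ± 0.22). The marker gene PR1 was lower by 3.99 ± 0.79 and 4.41 ± 0.81 log2 units, and the signalling gene PAD4 by 1.28 and 1.26. Of 28 salicylic-acid genes, 13 fell and 0 rose in batch 1 (20 adjusted over the list alone) and 22 fell and 0 rose in batch 2 (24 adjusted over the list alone). The medians were -1.26 and -1.72 (camera BH adjusted p = 1.2e-09 and 3.79e-17, adjusted p = 0.265 and 0.0521 with an estimated correlation). DMR6, which removes salicylic acid by hydroxylation, fell with them in batch 2 (-2.80 ± 0.37).

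Cold and drought genes ran the other way at 28 DAS, as 9 of 17 rose in Ler of batch 1 (12 adjusted over the list alone) and 4 in batch 2. COR15A, a chloroplast cryoprotectant gene, rose by 3.78 ± 0.61 in batch 1 and the dehydrin gene XERO2 by 4.34 ± 0.57 (3.15 without Ler B) and 2.91 ± 0.56. The list was called by camera in both batches (BH adjusted p = 2.13e-07 and 0.0158, adjusted p = 0.265 and 0.789 with an estimated correlation). Flavonoid genes rose by 7 of 18 in each batch, led by the MYB regulator PAP1 (2.99 ± 0.53 and 2.97 ± 0.53), camera BH adjusted p = 0.0129 and 0.000349, and adjusted p = 0.808 and 0.747 with an estimated correlation. Jasmonate genes had 3 rises and 0 falls in batch 1 (CORI3 by 1.79 ± 0.31) and no camera call (0.615). In batch 2 the jasmonate genes JMT (3.02 ± 0.62) and CORI3 (1.46 ± 0.31) were called higher and PR4 (-1.39 ± 0.42) lower. FT, the mobile floral signal, rose by 3.34 ± 0.72 and 4.28 ± 0.76 and SOC1 by 2.75 ± 0.29 and 2.25 ± 0.28, as FLC fell by 8.34 and 7.88. The batch 1 FT call was lost without C24 pool A. TGG2 fell from 1856 ± 43.1 to 3.27 ± 0.99 CPM in batch 1 and AOP3 rose by 9.33 ± 0.85. In all 1898 genes rose and 1871 fell in batch 1, 1701 and 1939 in batch 2, and 1096 rises and 1197 falls were shared. Batch 1 totals moved to 1876 (without C24 A) and 2052 (Ler B), and batch 2 totals to 2185 (C24 C), 2285 (C24 D), 2133 (Ler C) and 2349 (Ler D). With the replicate letter as a block batch 2 had 3439 rises and 3232 falls.

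The floral repressor FLM lay above the mid-parent in F1 seedlings of both crosses at 15 DAS. It held 19.5 ± 2.12 CPM in C24xLer (n = 2) and 4.50 ± 1.34 in the mid-parent (n = 2), 2.12 ± 0.33 higher (edgeR, BH adjusted p = 0.00704). In LerxC24 it held 21.1 ± 0.32 against 3.17 ± 0.05 CPM (2.74 ± 0.35, edgeR, BH adjusted p = 0.00617). MAF5, a relative of FLM and FLC, rose by 1.49 ± 0.22 in LerxC24, and the lectin genes MBP2 (-3.23 ± 0.46) and JAL23 (-2.15 ± 0.28) and the leucine-rich repeat gene FLR1 (-1.48 ± 0.18) fell. These 2 rises and 3 falls were all of the calls in batch 2 (1527 genes had an unadjusted p below 0.05, and DESeq2 called 84). Leaving out a library brought them to 0 without LerxC24 A, LerxC24 B or mid-parent C (1193, 2045 and 1048 genes below an unadjusted 0.05), and to FLR1 alone without mid-parent D. In batch 1, 4 genes rose and 55 fell, a total of 59 that became 32 without C24xLer A, 22 without C24xLer B and 31 with the replicate letter as a block. With the smallest Ler pools in place of Ler batch 1, an exchange chosen after the data were seen, 0 genes were called (1603 below an unadjusted 0.05), and 53 of the 55 falls were among the 362 genes that were lower in the smallest Ler pools than in Ler batch 1. With the parents averaged on the log scale, 111 rose and 47 fell in batch 1, and 132 and 30 in batch 2. The batch 1 FLM call was lost without C24xLer B or mid-parent B, with only the libraries of the batch, and with the smallest Ler pools (1.94, edgeR, BH adjusted p = 0.139). FLC itself did not pass in either F1 (0.55 ± 0.18 and 0.54 ± 0.18, edgeR, BH adjusted p = 0.734 and 0.723), but passed with the parents averaged on the log scale (2.59 and 3.03).

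Whole lists moved a little in the F1 seedlings. Flower-organ genes lay below the mid-parent in both hybrids (medians -0.65 and -0.68, 2 and 4 of 8 falling when adjusted over the list alone). None of those in LerxC24 passed over all genes. Camera called the flower-organ genes lower (BH adjusted p = 5.41e-07 and 2.04e-06), with adjusted p = 0.041 and 0.0571 with an estimated correlation. Cell-cycle genes were called lower in both (medians -0.22 and -0.14, camera BH adjusted p = 2.58e-09 and 2.67e-05, adjusted p = 0.223 and 0.73 with an estimated correlation). The cyclin CYCD3;3 fell by 0.73 ± 0.12 in C24xLer, 1 of 2 falls when adjusted over the list alone, a call lost without C24xLer B or mid-parent B, with only the libraries of the batch, and with the smallest Ler pools in place of Ler batch 1. Flavonoid genes were called lower in C24xLer (median -0.65) and LerxC24 (camera BH adjusted p = 2.19e-06 and 0.027, adjusted p = 0.195 and 0.83 with an estimated correlation). In C24xLer ethylene (median 0.42) and auxin genes were called higher and salicylic-acid genes lower (camera BH adjusted p = 0.00185, 0.0216 and 0.0117, adjusted p = 0.514, 0.712 and 0.712 with an estimated correlation). The auxin and salicylic-acid calls were lost with the smallest Ler pools (camera BH adjusted p = 0.147 and 0.239). In LerxC24 the 25 glucosinolate genes had a median of -0.45 and 9 fell when adjusted over the list alone (camera BH adjusted p = 3.3e-09, adjusted p = 0.0675 with an estimated correlation). None of the 9 passed over all genes.

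At 28 DAS the salicylic-acid genes of LerxC24 leaves fell well below the mid-parent as a group. The median of 28 genes was -1.10, and 0 passed over all genes and 21 fell when adjusted over the list alone (camera BH adjusted p = 1.49e-39, adjusted p = 0.00318 with an estimated correlation). PR1 held 137 ± 106 CPM in LerxC24 (n = 2) and 575 ± 172 in the mid-parent (n = 2), but it did not pass alone (-2.07 ± 0.72, edgeR, BH adjusted p = 0.891, and -0.82 with the parents averaged on the log scale). In C24xLer the same list had a median of -0.33 (camera BH adjusted p = 1.41e-06, adjusted p = 0.241 with an estimated correlation). In C24xLer cell-wall expansion genes were called higher (median 0.41, camera BH adjusted p = 0.000268, adjusted p = 0.0151 with an estimated correlation) and leaf-senescence genes lower (median -0.60, camera BH adjusted p = 3.42e-06, adjusted p = 0.0509 with an estimated correlation). Camera also called flowering and cold genes lower (BH adjusted p = 0.0018 and 1.02e-05) and photosynthesis, jasmonate and cell-cycle genes higher (0.00346, 0.0135 and 0.00607) in C24xLer, with adjusted p = 0.0509, 0.321, 0.443, 0.477 and 0.443 with an estimated correlation. The flowering and cold calls were lost with the parents averaged on the log scale (camera BH adjusted p = 0.254 and 0.177). In LerxC24 jasmonate genes (median 0.42), the PIF and shade genes, auxin and cold genes were called higher by camera (BH adjusted p = 3.21e-06, 0.00171, 0.0423 and 0.00689, adjusted p = 0.305, 0.268, 0.405 and 0.55 with an estimated correlation).

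Few single genes left the mid-parent at 28 DAS, 2 up and 2 down in C24xLer and 1 up and 7 down in LerxC24. AT3G01345, chosen by the largest rise in both hybrids, held 4.49 ± 0.17 CPM in C24xLer and 0.667 ± 0.020 in the mid-parent (2.75 ± 0.32, edgeR, BH adjusted p = 0.00939), and rose by 2.34 ± 0.32 in LerxC24. AT3G61198 and AT5G07650 fell in both hybrids (-2.16 ± 0.32 and -1.79 ± 0.26 in C24xLer, edgeR, BH adjusted p = 0.0401 and 0.0369), and the formin gene FH19 fell by 2.17 ± 0.28 in LerxC24. With the parents averaged on the log scale these values were -1.18, -1.12 and -1.19. FT did not pass (-2.14 ± 0.74 and -3.24 ± 0.77, edgeR, BH adjusted p = 1 and 0.264), though DESeq2 called it in LerxC24. Over the alternative settings FT ran from -2.31 to -1.35 in C24xLer and from -3.82 to -2.05 in LerxC24. The batch 1 calls fell to 0 without C24xLer A, C24xLer B, mid-parent A or mid-parent B (1014, 882, 596 and 685 genes below an unadjusted 0.05, against 764 with all libraries). In C24xLer the AT3G61198 call was also lost without any 1 library of L1-1, L2-1 or L2-2 and with crossed letters or log-scale averaging in the mid-parent, the AT5G07650 call without L2-1 A or L2-1 B, and both calls with the replicate letter as a block (8 calls in all) and with only the libraries of the batch. The batch 2 calls fell to 0 without LerxC24 A, LerxC24 B or mid-parent C (893, 847 and 458 genes, against 1087), to 1 without mid-parent D, to 5 without L4-2 A or L4-2 B, and to 0 with only the libraries of the batch. DESeq2 called 46 and 115 genes, and with the parents averaged on the log scale edgeR called 126 up and 8 down, and 149 and 16.

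Genes whose F1 level lay outside both parents included the same repressor. FLM exceeded C24 and Ler by 3.24 and 1.47 log2 units in C24xLer at 15 DAS, by 3.59 and 2.19 in LerxC24 at 15 DAS, and by 5.84 and 2.76 in C24xLer at 28 DAS, but was not called outside both parents in LerxC24 at 28 DAS, nor against the mid-parent in either hybrid at that age (3.62 ± 0.68 and 2.59 ± 0.65, edgeR, BH adjusted p = 0.15 and 0.33). In C24xLer seedlings SPL4, a promoter of flowering, lay below both (-1.78 and -2.17). In LerxC24 seedlings APR3, a sulfate-assimilation gene, lay below both parents (-2.44 and -2.24), as did LOX2, a jasmonate-synthesis gene (-1.68 and -1.51), and IMD1 and IPMI2 of glucosinolate chain elongation (-0.64 and -0.74, -0.75 and -0.69). These genes were chosen after values were seen. At 28 DAS the sucrose transporter gene SUC1 lay below both parents in LerxC24 (-0.91 and -1.06). In all 3 genes lay above and 5 below both parents in C24xLer at 15 DAS, 7 and 17 in LerxC24, 5 and 2 in C24xLer at 28 DAS, and 3 and 1 in LerxC24. The totals of 8, 24, 7 and 4 moved when a library was left out. At 15 DAS they became 3 (C24 A), 2 (C24 B), 4 (C24xLer A), 2 (C24xLer B) and 1 (Ler A) in batch 1, and 10 (C24 C), 6 (C24 D), 12 (Ler C), 11 (Ler D) and 11 (LerxC24 A) in batch 2. At 28 DAS they became 1 (C24xLer A), 4 (C24xLer B), 3 (C24 A), 3 (C24 B), 3 (Ler A) and 2 (Ler B) in batch 1, and 1 (LerxC24 A), 2 (C24 C) and 1 (Ler C) in batch 2. The batch 1 totals became 14 at 15 DAS with the smallest Ler pools in place of Ler batch 1, and 11 at 28 DAS with the replicate letter as a block.

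The L lines of batch 1 held far less of some transcripts at 15 DAS than the mid-parent. AT5G28450, 1 of the 5 largest falls, held 0.553 ± 0.112 CPM in the lines (n = 8 pools of 4 lines) and 62.8 ± 22.3 in the mid-parent (n = 2), -6.84 ± 0.15 (edgeR, BH adjusted p = 1.65e-15). It was abundant in C24 (96.1 CPM) and far lower in Ler pools other than those of batch 1. AT2G11240 (-10.6), SADHU1-1 (-9.59) and AT2G06950 (-7.56) fell further, and these were high only in the Ler pools of batch 1. AT3G62530 rose from 57.0 ± 3.54 to 172 ± 13.9 CPM (1.59 ± 0.21, and 0.97 with the smallest Ler pools in place of Ler batch 1). Flavonoid genes were called lower (median -0.46, camera BH adjusted p = 7.53e-05, adjusted p = 0.734 with an estimated correlation), with DFR of anthocyanin synthesis at -1.77 ± 0.38, a call lost without mid-parent A (-0.48), with the replicate letter as a block, with only the libraries of the batch or with the lines averaged as counts, and 2 falls among 18 genes (8 adjusted over the list alone). Auxin, photosynthesis and PIF and shade genes were called lower (medians -0.51, -0.30 and -0.54, camera BH adjusted p = 3.78e-06, 3.78e-06 and 0.00796), and ethylene genes higher (0.0247), each with adjusted p = 0.734 with an estimated correlation. The 2 mid-parent libraries differed widely at IAA29 (12.8 ± 13.2 CPM), YUC8 (2.18 ± 1.92) and PIF4 (62.5 ± 50.2), and lists were not retested with a library left out. FLC did not pass as an average of the 4 lines (-0.02 ± 0.14), and lay 2.03 higher with the parents averaged on the log scale. The line contrasts average lines on the log scale, so a line with little transcript weighs more than in the arithmetic mean. TGG2 is an example, at 428 ± 558 CPM in the lines and 928 ± 56.8 in C24xLer, a log2 difference of -3.21 ± 0.10 (-1.12 with the lines averaged as counts).

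Against C24xLer at 15 DAS, the same lines had 24 of 40 auxin genes lower when adjusted over the list alone, and 2 when adjusted over all genes. The median was -0.61 (camera BH adjusted p = 2.31e-10, adjusted p = 0.387 with an estimated correlation), and IAA16 fell by 0.42 ± 0.09, a call lost without C24xLer A, L1-1 A, L1-2 A, L2-1 A or L2-2 B, with the replicate letter as a block, with only the libraries of the batch or with the lines averaged as counts. PIF and shade genes were called lower (median -0.57, 2 falls), photosynthesis genes lower (median -0.34), and flower-organ (median 0.47) and cell-cycle genes higher (median 0.17, 2 rises, 3 adjusted over the list alone). Their camera BH adjusted p were 0.00017, 0.00017, 0.00017 and 0.000219, with adjusted p = 0.511, 0.605, 0.234 and 0.605 with an estimated correlation. Glucosinolate genes had a median of 0.44 and a mean of 0.01, with 2 falls over all genes and 12 rises and 3 falls when adjusted over the list alone (camera BH adjusted p = 0.0228, adjusted p = 0.605 with an estimated correlation). AOP3 fell by 3.39 ± 0.33 (39.3 ± 45.4 against 107 ± 45.4 CPM), a call lost with the lines averaged as counts. In all 68 genes rose and 355 fell against the mid-parent (295 and 394 with the parents averaged on the log scale, 55 and 136 with the lines averaged as counts), and 76 and 312 against C24xLer (15 and 72 with the lines averaged as counts). The first total became 186 without mid-parent A, and the second 150 without C24xLer A and 593 without C24xLer B.

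In batch 2 the L lines at 15 DAS had less FLC than both the mid-parent and the F1. They held 23.9 ± 8.56 CPM (n = 8), the mid-parent 52.3 ± 2.27 (n = 2) and LerxC24 76.2 ± 10.1 (n = 2), -1.21 ± 0.13 and -1.75 ± 0.13 (edgeR, BH adjusted p = 1.92e-05 and 1.1e-07). With the parents averaged on the log scale FLC lay 1.29 above the mid-parent. FLM rose by 2.08 ± 0.30 over the mid-parent (19.1 ± 11.9 against 3.17 ± 0.05 CPM), and MAF5 fell by 1.23 ± 0.16 against LerxC24. FRI, which activates FLC, rose by 0.58 ± 0.11 over the mid-parent, a call lost without mid-parent C or D or with the lines averaged as counts. MYB29 fell by 1.60 ± 0.13 and 1.15 ± 0.14 in the 2 comparisons, as the chain-elongation gene MAM1 rose by 0.68 ± 0.12 and 0.92 ± 0.12. The MAM1 call against the mid-parent was lost without mid-parent C or D. Of 25 glucosinolate genes 2 rose and 3 fell against the mid-parent (2 and 8 adjusted over the list alone), median -0.25 (camera BH adjusted p = 0.00291, adjusted p = 0.65 with an estimated correlation), a call lost with the parents averaged on the log scale (0.113) or the lines averaged as counts (0.0544). Flower-organ genes were called lower against the mid-parent (median -0.55, 1 fall, 5 adjusted over the list alone, camera BH adjusted p = 0.00121, adjusted p = 0.362 with an estimated correlation) and ethylene genes higher (median 0.50, camera BH adjusted p = 0.00121, adjusted p = 0.65 with an estimated correlation). ACS11 of ethylene synthesis rose by 2.08 ± 0.40, a call lost in the same 3 ways as that of FRI.

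Among all genes 123 rose and 461 fell in the batch 2 lines against the mid-parent at 15 DAS (1215 and 904 with the parents averaged on the log scale, 50 and 137 with the lines averaged as counts), and 145 and 421 against LerxC24 (70 and 155 with the lines averaged as counts). The largest falls were of genes near silence in the lines, such as AT5G26345 (0.281 ± 0.122 against 15.1 ± 1.06 CPM, -5.75 ± 0.39) and the retroelement SADHU5-2 (0.160 ± 0.084 against 5.50 ± 0.76 CPM, -5.23 ± 0.25), at -3.35 and -2.86 with the parents averaged on the log scale. The mid-parent total moved to 274 (mid-parent C) and 198 (mid-parent D), and the F1 total to 228 (LerxC24 A) and 238 (LerxC24 B). JAL23 rose by 1.19 ± 0.24 over LerxC24, a call lost without LerxC24 A or B.

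**Figure D1:**
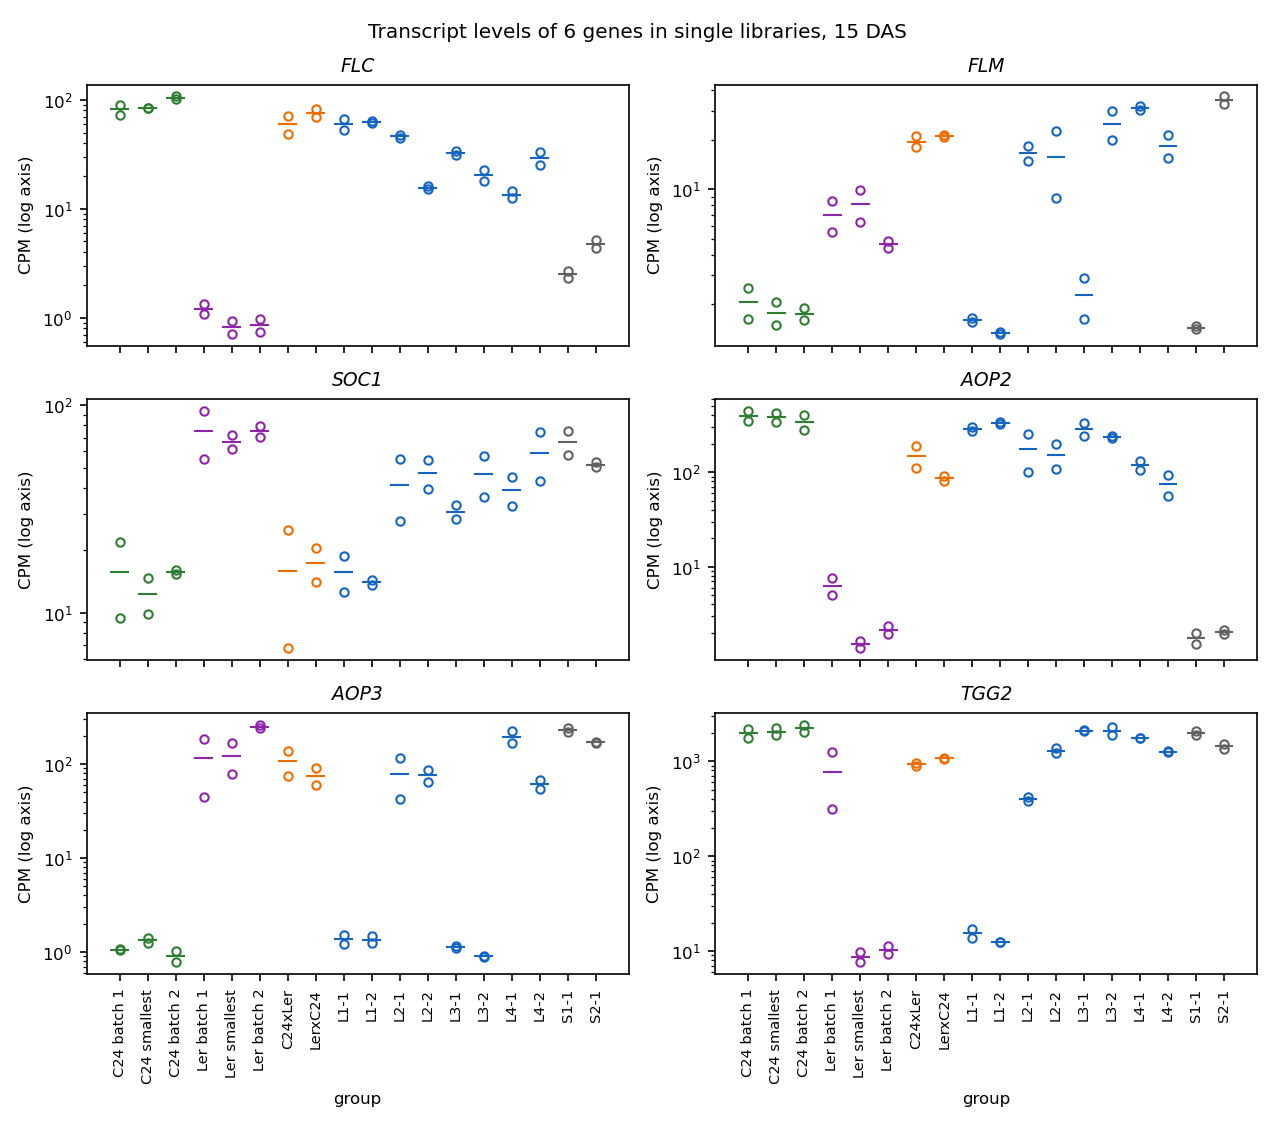
CPM (vertical axis, log scale) of 6 genes in each 15 DAS library, with 1 point per library, a bar at the group mean and groups along the horizontal axis. FLC lay at 3.63 ± 1.36 CPM in the S lines and 46.0 ± 20.3 CPM in the batch 1 L lines.

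At 28 DAS the batch 1 lines had more AOP2 and less AOP3 than the mid-parent, the 2 genes that shape aliphatic glucosinolate side chains. AOP2 held 648 ± 247 CPM in the lines (n = 8) and 275 ± 42.9 in the mid-parent (n = 2), 1.14 ± 0.22 (edgeR, BH adjusted p = 0.0217, lost without mid-parent A or B), and AOP3 99.8 ± 125 against 461 ± 55.0 (-4.56 ± 0.42). The glucosinolate list had 1 rise and 2 falls and a median of -0.28 (camera BH adjusted p = 0.000296, adjusted p = 0.42 with an estimated correlation). The repressor MAF4 fell by 1.32 ± 0.21, a call lost without mid-parent B. Flowering genes (1 fall, 1 rise and 6 falls adjusted over the list alone), cold genes (1 fall, 4 alone), senescence genes (1 fall, 2 alone) and salicylic-acid genes were called lower by camera (BH adjusted p = 0.00197, 0.000182, 0.00305 and 0.00193, adjusted p = 0.103, 0.346, 0.346 and 0.411 with an estimated correlation). These 4 list calls, the glucosinolate call and the AOP3 call (-0.91) were lost with the parents averaged on the log scale, where AOP2 lay 3.04 higher, and the AOP2, AOP3 and MAF4 calls with the lines averaged as counts. Photosynthesis (median 0.22), jasmonate and cell-wall genes were called higher (camera BH adjusted p = 0.000182, 0.000749 and 0.0151, adjusted p = 0.346, 0.346 and 0.103 with an estimated correlation). In all 12 genes rose and 204 fell against the mid-parent (215 and 118 with the parents averaged on the log scale, 9 and 37 with the lines averaged as counts), and 8 and 138 against C24xLer (4 and 23 with the lines averaged as counts). The totals became 104 (mid-parent A) and 102 (mid-parent B), and 91 (C24xLer A) and 88 (C24xLer B). SADHU10-1, a retroelement, held 0.793 ± 0.682 CPM in the lines and 12.2 ± 1.26 in C24xLer (-4.03 ± 0.33).

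In batch 2 at 28 DAS the L lines held almost no transcript of CSA1 and DAR4, consecutive resistance-type genes. At 15 DAS both were abundant in C24 and far lower in Ler pools other than those of batch 1 (CSA1 at 3.56 CPM in Ler and 94.3 in C24 of batch 2). The low level is therefore not particular to the lines. CSA1 held 0.190 ± 0.063 CPM in the lines (n = 8) against 44.6 ± 2.66 in the mid-parent (n = 2), and it fell against the mid-parent and LerxC24 (n = 2), -7.88 ± 0.20 and -7.33 ± 0.20 (edgeR, BH adjusted p = 2.63e-12 and 6.97e-12). DAR4 fell by 6.76 ± 0.22 and 6.67 ± 0.22. With the parents averaged on the log scale the values against the mid-parent were -4.87 for CSA1 and -4.18 for DAR4. FLC fell by 1.27 ± 0.15 and 1.89 ± 0.14 (1.66 above the mid-parent with the parents averaged on the log scale), and against LerxC24 the floral activators FUL (1.87 ± 0.26) and SOC1 (1.53 ± 0.25) and the flower-organ gene SEP1 (1.55 ± 0.28) rose. The SOC1 and SEP1 calls were lost without LerxC24 A or B, and the SEP1 call also with only the libraries of the batch or with the lines averaged as counts. The flower gene AG rose by 1.87 ± 0.28 over the mid-parent, a call lost without mid-parent C or D or with the lines averaged as counts. AT2G14460 had no reads in any line pool and 3.19 ± 0.07 CPM in the mid-parent, a call lost with the parents averaged on the log scale.

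The salicylic-acid list in these leaves was called lower than in the mid-parent and higher than in the F1. Against the mid-parent 7 of 28 fell (10 adjusted over the list alone), median -0.51 (camera BH adjusted p = 1.92e-09, adjusted p = 0.343 with an estimated correlation), with PCC1 at -1.59 ± 0.26, a call lost without mid-parent D or with only the libraries of the batch. Against LerxC24, 0 passed over all genes and 7 rose when adjusted over the list alone, median 0.52 (camera BH adjusted p = 1.69e-08, adjusted p = 0.187 with an estimated correlation). Jasmonate genes were called higher than the mid-parent (median 0.55, camera BH adjusted p = 0.000192, adjusted p = 0.343 with an estimated correlation), as were flower-organ genes (1 rise, 0.0285, adjusted p = 0.343 with an estimated correlation). Against LerxC24, flavonoid (median 0.89) and flower-organ genes were called higher and auxin genes (1 fall, 4 alone), glucosinolate genes (1 fall) and PIF and shade genes lower (camera BH adjusted p = 7.7e-05, 0.01, 0.00682, 0.0146 and 0.0271, adjusted p = 0.35, 0.187, 0.187, 0.686 and 0.35 with an estimated correlation). Totals were 60 rises and 315 falls against the mid-parent (469 and 320 with the parents averaged on the log scale, 22 and 86 with the lines averaged as counts), and 58 and 260 against LerxC24 (17 and 73 with the lines averaged as counts). They became 131 without mid-parent C and 131 without mid-parent D, and 164 (LerxC24 A) and 136 (LerxC24 B). With the replicate letter as a block the lines had 658 rises and 911 falls against LerxC24 (differences of A and B pools correlated between groups with r from 0.497 to 0.707).

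**Figure D2:**
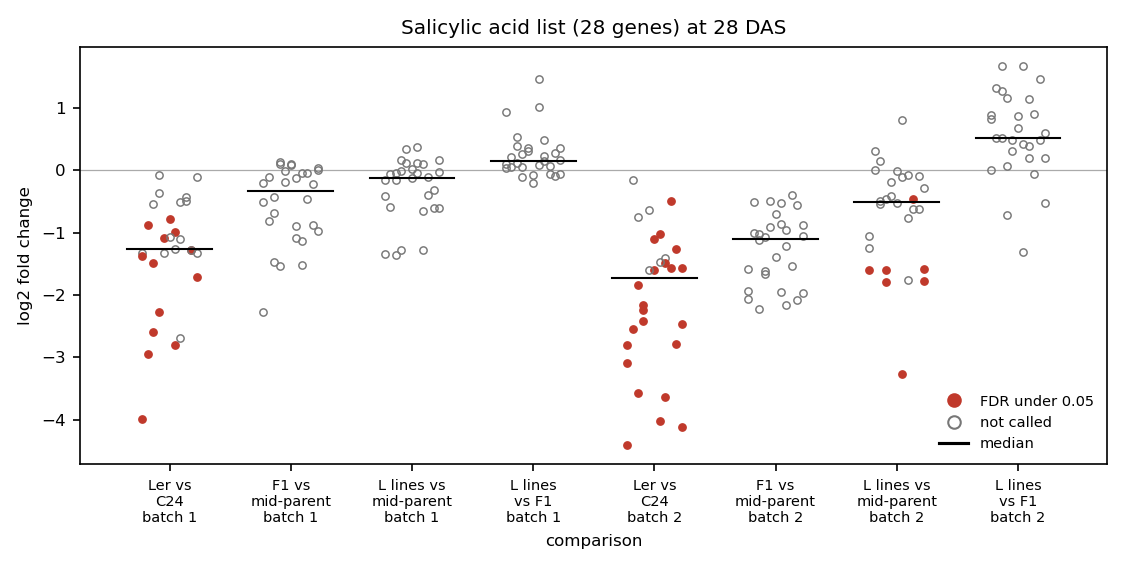
Log2 fold changes (vertical axis) of 28 salicylic-acid genes at 28 DAS in 8 comparisons, with 1 point per gene (filled where called) and a bar at the median. The median of LerxC24 lay at -1.10 and that of the batch 2 L lines at -0.51, each against the mid-parent.

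Most genes that set the L lines apart from the mid-parent were genes at which the parents differed. The share was 73.3 and 81.7% at 15 DAS and 95.8 and 89.6% at 28 DAS (batches 1 and 2), where 6.56, 18.8, 13.5 and 13.1% of tested genes differed between the parents. The parental calls and the mid-parent came from the same C24 and Ler libraries, which can itself raise these shares. Against the F1, which shares no library with the parents, the shares were 58.8, 76.1, 93.8 and 86.8%. Single lines gave between 33 calls (L2-1, 28 DAS) and 1528 calls (L4-2, 15 DAS, 811 up and 717 down) against the mid-parent. Genes that rose or fell in all 4 lines numbered 13 and 87 and 13 and 60 at 15 DAS, and 1 and 7 and 11 and 38 at 28 DAS. Lines moved in opposite directions at 89, 71, 14 and 7 genes. Across ages the lines shared 3 rises and 78 falls in batch 1 and 13 and 128 in batch 2, against 2.16 and 4.93 falls for independent lists. Across batches they shared 6 rises and 45 falls at 15 DAS and 2 and 36 at 28 DAS (5.44 and 2.32 falls for independent lists), and 41 and 12 genes moved in opposite directions. The numbers for independent lists, across ages and batches, spread the calls over all tested genes. Most calls lay at genes where the parents differed, so these numbers are too low a baseline for the overlap. The deviations of the batches had r = 0.101 at 15 DAS and 0.167 at 28 DAS, where the parental differences had r = 0.601 and 0.821.

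**Figure D3:**
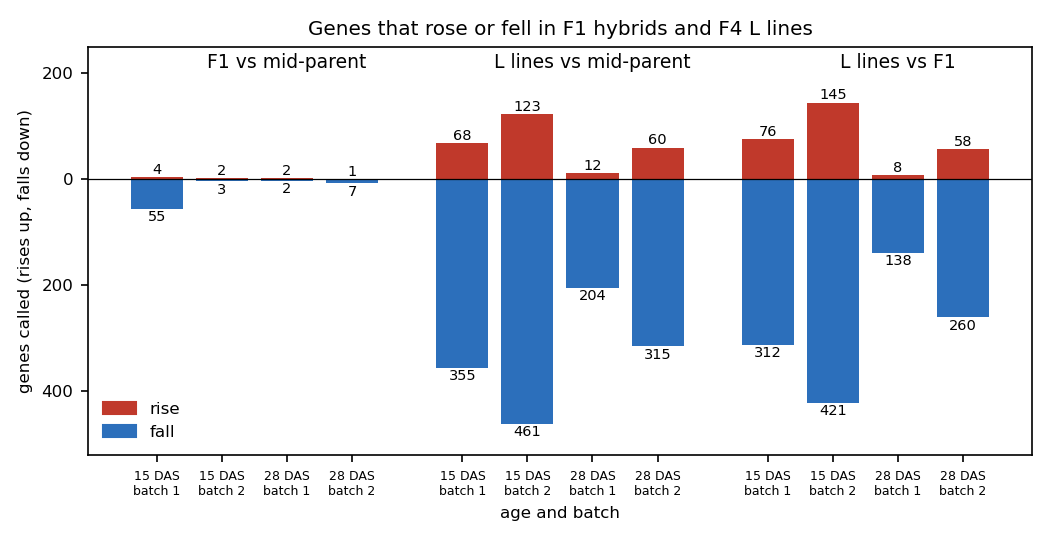
Genes called by edgeR (vertical axis, rises up and falls down) in the F1 against the mid-parent and in the L lines against the mid-parent and the F1, by age and batch. Falls outnumbered rises in each L line comparison, as in batch 2 at 15 DAS with 123 rises and 461 falls against the mid-parent.

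Genes moved alike by the F1 and the L lines of a batch were 0 up and 50 down, 1 and 3, 2 and 2, and 1 and 6 (15 DAS batches 1 and 2, 28 DAS batches 1 and 2). FLM rose and MBP2, JAL23 and FLR1 fell in both at 15 DAS in batch 2, and AT3G01345 rose in both at 28 DAS in each batch. Independent falls would have numbered 0.649, 0.046, 0.0147 and 0.0795, with calls spread over all tested genes and not only those where the parents differed. In 12 simulations with only the mid-parent shared the count was at most 0. With only the mid-parent shared few genes can be called at all, so this count followed from the design and cannot weigh the overlap. The 50 shared falls became 0 with the smallest Ler pools in place of Ler batch 1, and 27 with the replicate letter as a block. The deviations of F1 and lines had r = 0.54, 0.442, 0.51 and 0.384 (simulated 0.476, 0.494, 0.47 and 0.523) and covariance 0.0883, 0.0715, 0.0772 and 0.0685 (simulated 0.0262, 0.0352, 0.0428 and 0.0472), so part of the likeness may come from the shared mid-parent libraries. In batch 2 r lay below the simulated r at both ages, while the covariance lay above the simulated covariance in each set. Between the F1 of a batch and the lines of the other, which share no mid-parent library, r was 0.135 and 0.0896 at 15 DAS and 0.107 and 0.194 at 28 DAS (F1 of batches 1 and 2), with 2 rises and 0 falls, 0 and 1, 2 and 2, and 1 and 4 shared. The shared total of batch 1 at 15 DAS became 25 (C24xLer A) and 21 (C24xLer B), that of batch 2 0 (LerxC24 A, LerxC24 B or mid-parent C) and 1 (mid-parent D). At 28 DAS it became 0 without C24xLer A, C24xLer B, mid-parent A or mid-parent B in batch 1, and 0 (LerxC24 A, LerxC24 B or mid-parent C), 1 (mid-parent D) and 11 (L3-2 A) in batch 2.

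**Figure D4:**
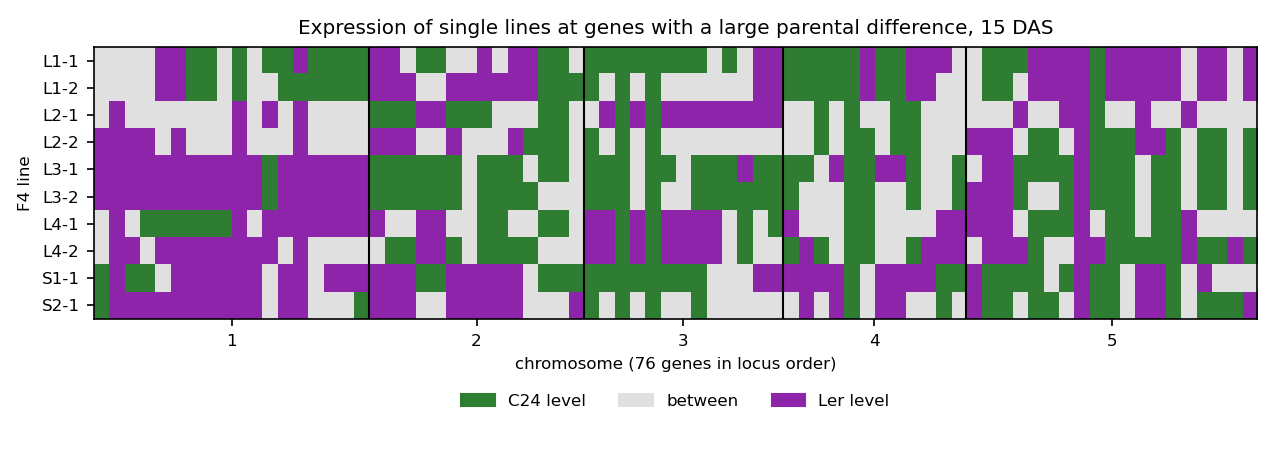
Level of 76 genes with a large parental difference in each F4 line at 15 DAS, with lines in order down the vertical axis, genes in locus order along chromosomes 1 to 5, and colour for the C24 level, the Ler level or a level between. L3-1 lay at the C24 level for 52.6% of the genes and S1-1 at the Ler level for 46.1%.

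The S lines had little FLC and more transcript of flower genes. FLC held 2.49 ± 0.26 CPM in S1-1 and 4.76 ± 0.58 in S2-1 (n = 2 each) against 41.0 ± 5.99 in the batch 1 mid-parent (n = 2), -4.04 ± 0.21 and -3.11 ± 0.20 (edgeR, BH adjusted p = 8.44e-10 and 2.51e-08), and -1.996 and -1.057 with the parents averaged on the log scale. FLM fell by 1.64 ± 0.35 in S1-1 and rose by 2.95 ± 0.34 in S2-1. SEP1, a flower-organ gene, rose by 1.21 ± 0.19 and 1.03 ± 0.19, the latter lost without S2-1 A, and AP3 by 1.80 ± 0.32 in S1-1, lost without mid-parent A. Flower-organ genes rose by 3 of 8 in S1-1 and 2 in S2-1 (6 each adjusted over the list alone, medians 1.15 and 0.81, camera BH adjusted p = 6.69e-07 and 1.28e-05, adjusted p = 0.0432 and 0.0925 with an estimated correlation). The light-harvesting gene LHCB1.4 fell by 1.83 ± 0.38 and 2.50 ± 0.39 (-3.428 and -4.095 against the batch 2 mid-parent). The FLM and LHCB1.4 calls of S1-1 were lost without mid-parent A, S1-1 A or S1-1 B, and the latter with the replicate letter as a block. Photosynthesis genes fell by 1 of 32 in S1-1 (14 alone) and 3 in S2-1 (16 alone), medians -0.57 and -0.60 (camera BH adjusted p = 8.22e-08 and 8.24e-09, adjusted p = 0.49 and 0.505 with an estimated correlation). AOP2 fell by 6.82 ± 0.48 in S1-1 (-4.82 with the parents averaged on the log scale).

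In S1-1 the flavonoid genes (2 rises and 1 fall, 9 and 1 alone, median 0.69) and salicylic-acid genes were called higher and auxin genes lower (median -0.48), camera BH adjusted p = 1.8e-06, 0.0072 and 2.61e-05, adjusted p = 0.188, 0.745 and 0.516 with an estimated correlation. In S2-1 ethylene genes were called higher (4 alone, camera BH adjusted p = 0.00227, adjusted p = 0.505 with an estimated correlation), and the auxin-synthesis gene TAA1 rose by 1.12 ± 0.19. Which S line grew in batch 1 is not given in the sources used here. With the batch 2 mid-parent the salicylic-acid and auxin calls of S1-1 and the ethylene call of S2-1 were lost (camera BH adjusted p = 0.384, 0.4 and 0.28), and with the mean of both mid-parents that of salicylic acid (0.0673). S1-1 and S2-1 then had 7237 and 7067 calls (batch 2) or 4281 and 3947 (mean of both), against 1015 and 841 with the batch 1 mid-parent. By this count both lines lay nearer to the batch 1 mid-parent. Over all genes S1-1 had 402 rises and 613 falls (932 and 782 with the parents averaged on the log scale) and S2-1 301 and 540 (874 and 602). The 2 lines shared 105 rises and 339 falls (r = 0.707), and both used the same mid-parent libraries. S1-1 gave 388 (mid-parent A), 536 (S1-1 A) or 503 (S1-1 B) calls, and S2-1 332 (mid-parent A), 340 (S2-1 A) or 508 (S2-1 B).

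Set directly against the batch 1 L lines at 15 DAS, the S lines had 1834 genes higher and 1486 lower. The protocols place 1 S line in batch 1, so these counts and list calls may also hold a difference between batches. That difference reached 4320 genes in C24 and 5600 in Ler. Yet both S lines had fewer calls against the batch 1 mid-parent (1015 in S1-1 and 841 in S2-1) than against that of batch 2. FLC held 3.63 ± 1.36 CPM in the S lines (n = 4) and 46.0 ± 20.3 in the L lines (n = 8), -3.56 ± 0.14 (edgeR, BH adjusted p = 8.45e-12). FRI fell by 0.88 ± 0.08, and FT and the flower identity gene AP1 rose by 1.52 ± 0.22 and 1.84 ± 0.24. Of 8 flower-organ genes 7 rose (8 alone), median 0.98 (camera BH adjusted p = 2.31e-09, adjusted p = 0.0121 with an estimated correlation). Of 18 flavonoid genes 14 rose (14 alone), median 1.04 (camera BH adjusted p = 1.28e-09, adjusted p = 0.0462 with an estimated correlation), led by FLS1 (1.13 ± 0.14), LDOX (1.90 ± 0.25) and F3H (1.24 ± 0.19). In the glucosinolate list 3 rose and 10 fell (4 and 14 alone, median -0.36), with AOP3 up by 4.28 ± 0.29, TGG2 up by 4.07 ± 0.09 and AOP2 down by 6.89. The TGG2 levels of S and L libraries overlapped (12.6 to 17.2 CPM in L1-1 and L1-2, but 1221 and 1361 in L2-2 and 1342 to 2061 in the S lines), and its rise was 2.00 against all 8 L lines. The cryoprotectant gene COR15A fell by 3.22 ± 0.71 (2.51 with the replicate letter as a block).

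Photosynthesis genes had 4 falls in the S lines against the L lines (6 alone, median -0.28), such as LHCB1.4 (-1.61 ± 0.24). Salicylic-acid genes had 3 rises (3 alone) and meristem genes 2 (3 alone), with KNAT2 up by 0.46 ± 0.10. Camera BH adjusted p were 0.0409 for glucosinolate, 0.00074 for photosynthesis, 0.00341 for salicylic-acid and 0.0409 for meristem genes, with adjusted p = 0.632, 0.632, 0.674 and 0.546 with an estimated correlation. Against all 8 L lines the glucosinolate, salicylic-acid and meristem calls were lost (camera BH adjusted p = 0.629, 0.484 and 0.238). CBP60G, an activator of ICS1, rose by 1.70 ± 0.42, a call lost without S2-1 A or against all 8 L lines. The 3320 calls became 2153 without S1-1 B and 2093 without S2-1 A.

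The smallest Ler seedlings had less transcript of TGG2 than Ler pools of the same batch. It held 8.74 ± 1.58 CPM in the smallest Ler pools (n = 2) and 776 ± 650 in Ler (n = 2), -6.47 ± 0.42 (edgeR, BH adjusted p = 1.1e-09). AT2G11240 and SADHU1-1 had no reads in the smallest Ler pools and 159 ± 84.9 and 44.3 ± 22.0 CPM in Ler. Against Ler of batch 2 the TGG2 call was lost (-0.24, edgeR, BH adjusted p = 0.321), and neither of the other genes had reads. In all 31 genes rose and 362 fell, becoming 252 (Ler A), 236 (smallest Ler A) or 258 (smallest Ler B). Glucosinolate genes had 3 falls (6 alone), median -0.18 (camera BH adjusted p = 0.00205, adjusted p = 0.686 with an estimated correlation). The smallest C24 seedlings had 0 calls by edgeR (450 genes below an unadjusted 0.05, DESeq2 0). The B library of these seedlings and that of C24 lay closer to each other than any other pair of the age, and it is not given in the sources used here whether they shared plants or RNA. Without both of them 0 genes were called (797 below an unadjusted 0.05). Root-marker genes were called higher there (4 alone, median 0.33, camera BH adjusted p = 6.97e-07, adjusted p = 0.108 with an estimated correlation), and FLC did not move (84.1 ± 0.95 against 81.5 ± 12.3 CPM).

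Between the batches, which were grown under different light tubes, C24 differed at 15 DAS in the cell-cycle list. Its genes were called lower in C24 of batch 2 (12 of 31, 16 alone, median -0.38), camera BH adjusted p = 3.34e-08 and adjusted p = 0.555 with an estimated correlation. CDKB1;2, a mitotic kinase gene, fell by 0.85 ± 0.14 in C24 and 1.47 ± 0.14 in Ler, and PCNA2 of DNA replication by 0.74 and 1.22 (n = 2 and 2). The Ler falls were 0.52 and 0.87 with the smallest Ler pools in place of Ler batch 1. Flavonoid genes fell in C24 (1 rise, 8 falls, 1 and 13 alone, median -0.85), with FLS1 at -1.91 ± 0.32, and salicylic-acid genes rose (4, median 0.89), camera BH adjusted p = 0.000243 and 0.00125, adjusted p = 0.555 and 0.667 with an estimated correlation. Auxin genes (1 rise, 7 falls) and root-marker genes were called lower in C24 (camera BH adjusted p = 0.0197 and 0.0214, adjusted p = 0.733 and 0.585 with an estimated correlation), for example the nitrate transporter gene NRT2.1 of the root markers (-1.24 ± 0.27). Clock genes had 3 rises and 1 fall and no camera call (0.216). C24 had 1972 rises and 2348 falls and Ler 2420 and 3180. The C24 total became 2168 (batch 1 A), 2145 (batch 1 B), 1977 (batch 2 C) or 1612 (batch 2 D), and the Ler total 2505 (batch 1 A), 3347 (batch 2 C) or 2655 (batch 2 D).

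At 28 DAS the batches differed in light-harvesting and clock genes. LHCB2.1 held 2134 ± 424 CPM in C24 of batch 2 (n = 2) and 22.2 ± 0.08 in batch 1 (n = 2), 6.59 ± 0.40 (edgeR, BH adjusted p = 2.11e-08), and it rose by 5.62 ± 0.38 in Ler. The clock genes PRR9 and LNK2 rose by 8.07 ± 0.53 and 4.99 ± 0.48 in C24 and by 6.94 ± 0.48 and 5.46 ± 0.49 in Ler, and TOC1, an evening gene, fell by 2.54 ± 0.62 and 2.95 ± 0.63. The C24 TOC1 call was lost without any 1 of the 4 C24 libraries, and the Ler call without batch 2 C. Of 32 photosynthesis genes 23 rose and 0 fell in C24 (25 and 1 alone, median 2.35) and 22 rose in Ler (25 alone, median 1.97), camera BH adjusted p = 6.8e-33 and 1.3e-30, adjusted p = 0.00199 and 0.00282 with an estimated correlation. Clock genes had 8 rises and 3 falls in C24 and 7 and 4 in Ler (9 and 5 alone) with no camera call (0.0695 and 0.0552).

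Auxin genes rose by 12 of 40 in C24 (13 alone, median 0.88) and 6 in Ler (8 alone), SAUR15 by 3.43 ± 0.49 in C24, camera BH adjusted p = 3.74e-07 and 0.000151, adjusted p = 0.0181 and 0.0673 with an estimated correlation. Salicylic-acid genes fell by 10 of 28 in C24 (1 rise and 11 falls alone, median -0.83) and 13 in Ler (14 alone, median -0.97), with WRKY70 at -1.49 ± 0.29 and -2.47 ± 0.30, camera BH adjusted p = 6.53e-07 and 6.58e-13, adjusted p = 0.167 and 0.0673 with an estimated correlation. PIF and shade genes rose by 5 of 17 in each (6 alone), PIF5 by 3.32 ± 0.28 and 3.91 ± 0.29, camera BH adjusted p = 5.84e-05 and 0.000151, adjusted p = 0.0543 and 0.0673 with an estimated correlation. In C24 cell-wall (8 rises, 1 fall) and glucosinolate genes (4 rises, 13 alone) were called higher (camera BH adjusted p = 0.00367 and 1.16e-05, adjusted p = 0.0266 and 0.363 with an estimated correlation), and in Ler cold genes lower (1 rise, 4 falls, 1 and 7 alone, 0.0136, adjusted p = 0.504 with an estimated correlation). C24 had 1186 rises and 1151 falls and Ler 1183 and 1365. The C24 total became 862 (batch 1 A), 1131 (batch 1 B), 1017 (batch 2 C) or 1034 (batch 2 D), and the Ler total 1445, 1328, 1337 or 1339 without the same libraries of Ler.

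**Figure D5:**
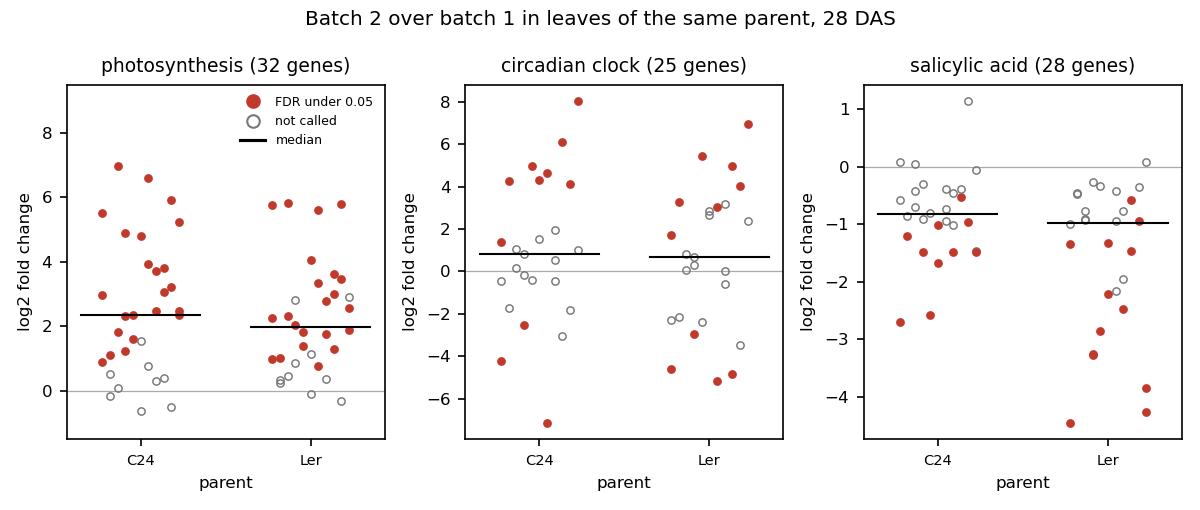
Log2 fold changes (vertical axis) of batch 2 over batch 1 at 28 DAS for photosynthesis, clock and salicylic-acid genes in C24 and Ler, with 1 point per gene (filled where called) and a bar at the median. The photosynthesis medians lay at 2.35 in C24 and 1.97 in Ler.

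The deviation of the F1 from its mid-parent was compared between batches, where each batch held 1 direction of the cross. At 15 DAS 10 genes had a higher and 2 a lower deviation in batch 2, among them AT5G28919 and AT5G28920 (4.84 ± 0.57 and 4.61 ± 0.55, edgeR, BH adjusted p = 0.00146 each), which cannot be told apart. Both genes were high in Ler of batch 1 alone (31.8 and 19.9, and 31.9 and 20.1 CPM in pools A and B, at most 1.33 in any other parent library). The 2 differences were 0.36 and 0.21 with the smallest Ler pools in place of Ler batch 1, where 0 genes were called (350 below an unadjusted 0.05), and both calls were lost with the parents averaged on the log scale. The FLC deviation did not differ (-0.00 ± 0.26). The 12 calls became 5 (C24xLer A), 4 (C24xLer B), 3 (LerxC24 A), 7 (mid-parent B), 4 (mid-parent C) or 5 (mid-parent D). Glucosinolate genes were called lower in batch 2 (camera BH adjusted p = 4.95e-05, adjusted p = 0.678 with an estimated correlation). At 28 DAS edgeR called 0 genes (343 below an unadjusted 0.05, DESeq2 2). Salicylic-acid genes had a lower deviation in batch 2 (median -0.69), cold genes a higher (median 1.29, 2 alone) and senescence genes a higher one (camera BH adjusted p = 6.95e-14, 6.53e-10 and 0.000145, adjusted p = 0.122 each with an estimated correlation).

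Between ages the F1 deviation was higher at 28 DAS for 9 genes and lower for 2 in batch 1, and higher for 3 and lower for 3 in batch 2. AT5G36930, chosen by its adjusted p, had a deviation 1.91 ± 0.25 higher in batch 1 (edgeR, BH adjusted p = 0.000223). It was 0.21 with the smallest Ler pools in place of Ler batch 1, where 0 genes of batch 1 were called (894 below an unadjusted 0.05). MBP2, a lectin gene, had a higher deviation in batch 2 (edgeR, BH adjusted p = 0.00974), a call lost without 15 DAS LerxC24 B, 28 DAS LerxC24 A, or 28 DAS mid-parent C or D. The batch 1 total became 7 (15 DAS C24xLer A), 6 (15 DAS C24xLer B), 6 (28 DAS C24xLer A), 7 (28 DAS C24xLer B), 7 (28 DAS mid-parent A) or 7 (28 DAS mid-parent B). The batch 2 total became 2 (15 DAS LerxC24 B), 1 (28 DAS LerxC24 A), or 0 without 28 DAS mid-parent C or D (692 and 1286 genes below an unadjusted 0.05). In batch 1 cell-cycle genes deviated more upward at 28 DAS and senescence genes more downward (camera BH adjusted p = 8.12e-10 and 1.28e-05, adjusted p = 0.0963 and 0.0643 with an estimated correlation). In batch 2 salicylic-acid genes deviated more downward (median -0.90) and jasmonate genes more upward (3 alone), camera BH adjusted p = 1.62e-11 and 1.02e-05, adjusted p = 0.284 each with an estimated correlation.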

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

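The tests of F1 deviations were planned, and those of small size in Ler minus C24 and of the Ler pools of batch 1 were chosen only after the data were seen. The F1 deviation from the mid-parent differed between batches at 12 genes at 15 DAS (10 higher and 2 lower in batch 2). It differed between ages at 11 genes in batch 1 and 6 genes in batch 2. The effect of small size differed between Ler and C24 at 155 genes, 2 higher and 153 lower in Ler. All of these tests but that of batch 2 between ages used the Ler pools of batch 1 at 15 DAS.

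Those Ler pools carried transcripts that other Ler pools lacked or held at a far lower level. TGG2, a myrosinase gene, lay at 63.6 and 16.6% of its C24 level in pools A and B, and the median of genes abundant in C24 and far lower in other Ler pools at 36.6 and 20.3%, yet FLC lay at 1.67 and 1.38% and AOP2 at 1.95 and 1.31%. The retrotransposon-related gene AT2G11240 held 101 and 228 CPM. Admixture of C24 was tested in 3 ways in turn: 9 of 19 genes at 1 CPM or more in these Ler pools and under 0.1 CPM in other Ler pools were also under 0.1 CPM in every C24 pool, and 32% of genes abundant in C24 lay under 0.25 of the share of TGG2, neither of which decided, while 26 genes lay over 4 times above all C24 and other Ler libraries, which a mix of C24 and Ler RNA forbids. Small size as the source of the 362 falls of the smallest Ler seedlings met the median of 0.067 log2 between batch 2 Ler and those seedlings at the same genes, against a median fall of 1.79. Plants of another genotype in the pools remain a candidate explanation, as 6 genes lay at 1 CPM or more in both pools and under 0.1 CPM in every library of the other groups of the age.

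With the smallest Ler pools in place of these Ler pools, the F1 calls of batch 1 at 15 DAS went from 59 to 0, those shared with the L lines from 50 to 0, the 12 genes between batches to 0 and the 11 between ages to 0. Of the 55 falls in C24xLer, 53 were among the 362. The calls between Ler and C24 rose from 1987 to 3089.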

How the results depend on the processing

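Lines averaged as counts, exchanged Ler pools and the omission of both B libraries of C24 and the smallest C24 were chosen after the data were seen, and the other alternatives were planned. Of 557 alternative counts of called genes, 363 stayed within 1.5 times the main count. Of 833 alternative values of called lists 782 stayed called in the same direction, 51 were no longer called and 0 reversed. All of these list values kept the preset correlation, and lists were not retested with DESeq2 or with a library left out. The tally therefore does not cover the estimated correlation, with which most list calls above were lost. For 153 fold changes of named genes 2040 of 2197 values kept their direction and side of the threshold, 151 lost the call, 3 gained one and 3 reversed. Named genes were picked with preference for calls held without each library, so that choice raises this share and it does not describe called genes at large. Size factors of DESeq2 in edgeR, no filter, nuclear genes only and crossed letters moved no count by over 1.5 times. Depth limits the rare transcripts, the 2 pools per group limit the tests, and a lone pool after an omission was assumed to vary like the other groups. The cause was not tested where none is named. Pairs are given as 15 DAS batches 1 and 2, then 28 DAS batches 1 and 2.

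DESeq2 gave 84, 46 and 115 F1 calls against the mid-parent (15 DAS batch 2, 28 DAS batches 1 and 2), and 16, 38, 16 and 11 genes outside both parents. It gave 906, 376 and 670 L line calls against the mid-parent (15 DAS batch 2, 28 DAS batches 1 and 2), 784 and 619 against the F1 (15 DAS batch 1, 28 DAS batch 2), and 34, 31 and 60 genes shared by F1 and L lines. S1-1 and S2-1 had 1587 and 1376, the F1 deviation 21 and 2 between batches at 15 and 28 DAS, and 25 and 27 between ages.

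With the mid-parent as a log-scale mean, which is lower than the arithmetic mean where parents differ, F1 calls were 158, 162, 134 and 165, L line calls 689, 2119, 333 and 789, shared genes 84, 77, 68 and 93, S1-1 and S2-1 calls 1714 and 1476, F1 deviations 37 between batches at 15 DAS and 58 and 32 between ages. FLC in the L lines reversed to 2.03 and 1.29 (15 DAS) and 1.66 (28 DAS batch 2). With the lines averaged as counts, L line calls were 191, 187, 46 and 108 against the mid-parent and 87, 225, 27 and 90 against the F1.

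Only the libraries of the batch, so fewer samples, gave 19, 8 and 0 F1 calls (15 DAS batches 1 and 2, and 28 DAS batch 2, with 1080 genes below an unadjusted 0.05), 1 and 37 genes outside both parents at 15 DAS, 250 and 162 L line calls (15 DAS batch 1, mid-parent and F1), 19 and 0 shared genes (15 DAS batch 1, 28 DAS batch 2), and 258 in the smallest Ler seedlings. The letter as a replicate block gave 31 and 8 F1 calls (15 and 28 DAS batch 1), 27 shared genes, 11 outside both parents (28 DAS batch 1), 6671 between the parents and 1569 for L lines against the F1 (28 DAS batch 2). Differences of A and B pools correlated between groups with medians of 0.332, 0.166, 0.265 and 0.615.

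With the smallest Ler pools in place of Ler batch 1 at 15 DAS, Ler against C24 gave 3089, the F1 0 (1603 genes below an unadjusted 0.05), shared genes 0, genes outside both parents 14, and F1 deviations 0 between batches and 0 between ages (350 and 894 below an unadjusted 0.05). With Ler batch 2 in their place the smallest Ler seedlings had 6046 calls, and AT2G11240 and SADHU1-1 went to 0 as neither had reads in either group. With the mid-parent of batch 2, S1-1 and S2-1 had 7237 and 7067 calls, with the mean of both mid-parents 4281 and 3947, and the S lines against all 8 L lines 10403, values that also hold the batch difference.

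With 1 library left out, calls between the parents ran from 1089 to 1479, 2964 to 3647, 1876 to 2668 and 2133 to 2349, F1 calls from 22 to 65, 0 to 7, 0 to 5 and 0 to 11, genes outside both parents from 1 to 6, 6 to 28, 1 to 4 and 1 to 4, L line calls against the mid-parent from 186 to 615, 198 to 734, 102 to 235 and 131 to 383, against the F1 from 150 to 593, 228 to 611, 88 to 145 and 136 to 333, and shared genes from 21 to 64, 0 to 6, 0 to 5 and 0 to 11. S1-1 ran from 388 to 1077, S2-1 from 332 to 871, S against L lines from 2093 to 3609, and the smallest Ler seedlings from 236 to 372. Between batches C24 ran from 1612 to 2168 and Ler from 2505 to 4759 at 15 DAS, and 862 to 1131 and 1328 to 1445 at 28 DAS. F1 deviations ran from 3 to 14 between batches at 15 DAS, and from 6 to 11 and 0 to 6 between ages.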

Other observations

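The tests of harvest hour and of averaging lines and the comparison of line levels were chosen only after the results were seen, and those of the arithmetic mid-parent, light tubes and other splits before. FLM divided the F4 lines at 15 DAS. It held 34.8 ± 2.55 CPM in S2-1 and 1.44 ± 0.04 in S1-1. In the L lines it held 16.6 ± 2.44, 15.7 ± 9.60, 24.9 ± 7.04, 31.1 ± 1.25 and 18.4 ± 4.08 CPM in L2-1, L2-2, L3-2, L4-1 and L4-2 (n = 2 each), against 1.61 ± 0.07, 1.34 ± 0.03 and 2.26 ± 0.91 CPM in L1-1, L1-2 and L3-1, 1.75 ± 0.21 in C24 and 4.62 ± 0.33 in Ler of batch 2. The lines L2-2 and L4-1 kept the higher level at 28 DAS (17.2 ± 0.88 and 34.1 ± 2.81 CPM), and L1-1 and L1-2 the lower (0.226 ± 0.152 and 0.243 ± 0.031 CPM). FLC, the other repressor, ran over the L lines from 13.5 ± 1.301 CPM in L4-1 to 62.5 ± 2.04 in L1-2 at 15 DAS, and lay lower in S1-1 and S2-1. These genes were chosen after values were seen.

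At genes with a log2 difference of at least 4 between the parents, the F4 lines sat near 1 parent far more often than the F1. Of 76 genes at 15 DAS, L3-1 lay at the C24 level for 52.6%, S1-1 at the Ler level for 46.1% and L2-1 between the parents for 52.6%, and C24xLer and LerxC24 lay between for 96.1 and 85.5%. Only 3 genes were C24-like and 1 Ler-like in all 8 L lines. At 28 DAS the libraries matched their own line at 92.6 to 100% of the genes that lay at a parental level at both ages, 23 to 45 per library. Genes between the parents were left out of these shares. By these shares L1-2 B matched L1-1, and L3-2 A matched L3-1, as well as its own line (100%). With genes between the parents counted, these lines differed at 28 DAS. On chromosome 3, L1-1 was C24-like for 80% and between for 0% of genes, and L1-2 for 0 and 80%. On chromosome 4, L3-1 was Ler-like for 30% and L3-2 for 0%. The L4-2 B library, with a doubtful label, matched L4-2 at 93.9% of 33 genes and any other line at up to 81%.

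Falls outnumbered rises in the L lines against the mid-parent, by 83.9, 78.9, 94.4 and 84.0% of calls (15 DAS batches 1 and 2, 28 DAS batches 1 and 2). Averaging lines on the log scale lowers the level of a gene silent in some lines. With lines averaged as counts falls still made up at least 71.2% of calls, but their number dropped. Falls went from 355, 461, 204 and 315 to 136, 137, 37 and 86, and rises from 68, 123, 12 and 60 to 55, 50, 9 and 22. The number of called falls thus depended on how the lines were averaged. At genes with no called parental difference falls were 75.2, 63.6, 44.4 and 43.6% (85 falls and 28 rises, 68 and 39, 4 and 5, 17 and 22), and with the parents averaged on the log scale rises outnumbered falls in 3 sets (1215 and 904, 215 and 118, 469 and 320) but not in 15 DAS batch 1 (295 and 394). The arithmetic mid-parent of unequal parents may therefore account for part of the excess, and over the 4 sets together the test did not decide. Fixation of the low parental allele in a line was not tested.

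Clock genes set the 28 DAS batches apart in both parents. Morning genes minus evening genes had a median batch difference of 3.09 log2 in C24 and 5.85 in Ler (11 and 8 genes), against -1.60 and -1.12 at 15 DAS. Light tubes that act alike at both ages would give a positive correlation of clock genes between ages. The r was -0.702 in C24 and -0.588 in Ler (25 genes). With the harvest hour unknown at both ages, shifts in hour could hide an effect of the tubes, so this r cannot decide. A harvest at another hour of the day may explain the 3.09, and would also touch light-harvesting and PIF genes. The clock gene LHY also differed between pools within batch 2 at 28 DAS (129 ± 145 CPM in Ler, 66.5 ± 76.1 in C24 and 82.4 ± 96.4 in LerxC24). In batch 1 it held 14.2 ± 0.49 CPM in Ler and 17.0 ± 1.84 in C24. The hour of harvest is not given in the sources used here.

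The S lines and the batch 1 L lines gave 2057 calls in a fit of their 12 libraries. Of 100 drawn splits (of 495) 1 reached that number, the real one, with 1 call in the next highest. The protocols place 1 S line in batch 1, so the 2057 calls may also hold a batch difference. Most drawn splits parted the pools of a line, which itself lowers the calls, so they say little about differences between lines. Splits that keep whole lines together number 15, so their smallest share is 0.0667.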
